A study of Homo sapiens with 6 samples.

How the data were processed

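The series holds 6 one-colour Agilent arrays of HET-1A cells, 3 from cells given vehicle (water) and 3 from cells given hydroxyl-modified graphene quantum dots (GQD) at 50 μg/mL for 24 h. Per the labels' protocols, the dishes were treated in triplicate, total RNA was extracted, and Cy3-labelled cRNA was made with a low-input linear amplification kit, in which priming from the poly(A) tail is the usual design. The labels do not say whether the 3 arrays of a group came from separate cultures, so the p-values measure the spread between these arrays, which may be technical. Groups and replicate numbers were taken from the sample titles.

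Per the file headers, each scanner file was made with Agilent Feature Extraction 10.7.1.1, the version that the submitters' processing notes also name, and holds spot intensity values for 62976 spots. Per the file headers, the processed intensity used here was background-subtracted and spatially detrended, with low values replaced by a surrogate, and was not scaled between arrays. The deposited series table holds log2 values with the same median (3.92), quartiles (1.97 and 7.43), minimum and maximum in all 6 columns. The sorted values of each column differed from those of the first by at most 0.00735, so that the authors' values had been scaled to a common distribution between arrays. Set against the scanner signals of 23354 probes well above background on all arrays, these columns had a slope of 0.981 to 1.02 per log2 unit and a correlation of 0.9996 to 0.9999 across probes, which are not independent replicates. Scale, centring and direction of the deposited table were therefore known, and it was used as an alternative.

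Control spots and outlier-flagged spots were left out and the spots of a probe were averaged, which left 58201 probes, of which 4 had a missing value on an array and were not tested. Probe coordinates are those of the files, on build hg19 (GRCh37). Gene names were updated with a RefSeq gene table of another build, which was used for names only. A symbol was found by accession for 31104 probes, by symbol for 3366 and by an unambiguous older symbol for 496, together 23556 genes. The other 23235 probes had no symbol and were tested separately. The processed intensities were log2-transformed and the 75th percentile of each array was subtracted. Probes well above background on at least 3 of the 6 arrays were kept, and each of 16105 genes was represented by its brightest probe.

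The 75th percentile of the processed intensity was 184 to 220 on the vehicle arrays and 133 to 175 on the GQD arrays, and 26456 to 29726 probes per array were well above background. No spot was saturated. The number of arrays limits the precision. The files showed that the arrays lay on 2 slides, scanned separately. Slide 1 held vehicle 3 and all 3 GQD arrays, and slide 2 held vehicle 1 and vehicle 2. A fit with slide as a block therefore estimates the treatment from slide 1, where it compares 1 vehicle array with 3 GQD arrays.

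Groups were compared with limma 3.58.1 (lmFit and eBayes, two-sided) in R 4.3.3, with Benjamini-Hochberg adjustment over genes and a threshold of 0.05 on the adjusted p. Genes changed by at least 2-fold were counted as well. Of 37 gene lists fixed before the data were examined, with 796 of their 843 genes measured, the 35 with at least 5 measured members were tested with camera at its preset correlation of 0.01, with an estimated correlation, and with fry. Named genes followed a rule fixed before the data were examined. It took the 12 largest rises and the 12 largest falls among called genes that were well above background on all 6 arrays, had no overlap between groups and had an established symbol. It added the 4 genes per direction with the highest fold among those well above background on all arrays of one group and none of the other, and up to 4 called members per list by size of change. Of the genes so chosen, 4 are not reported here, and no others were put in their place. For a gene not well above background in one group, the fold is given as "at least", from the mean of the brighter group against the mean, per array, of the higher of the gene's own signal and the lowest signal called well above background.

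The steps were tested on simulated arrays with the means and spreads of the 16105 genes, of which 200 were changed. limma called 94.1% of the genes lowered by 2 log2 units, 97% of those raised by 2, 64.7% of those lowered by 1, 66.7% of those raised by 1, 21.2% of those lowered by 0.5 and 12.1% of those raised by 0.5, and 8 of 15905 unchanged genes. In the data 11203 genes were called, so an adjusted p under 0.05 stands for a less strict p there. The simulated shares need not hold for the data. In simulated lists, camera found the 1 shifted list of 35 and called no other. This too need not hold for the data, where no list passed with an estimated correlation.

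Alternatives fixed before the data were examined were quantile normalization, centring on the median of tested genes, normexp background correction (offset 50) with either scaling, the deposited log2 table, other filters on dim probes, the mean of a gene's probes, an intensity trend, array weights, slide or replicate number as a block, and leaving out each array. Alternatives added after seeing the data were scaling to the spike-in probes, the probe nearest the 5′ or the 3′ end of a gene, and slide 1 alone.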

Results

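Gene expression was measured in HET-1A, an immortalised line of human esophageal epithelial cells, after 24 h with hydroxyl-modified graphene quantum dots (GQD, carbon nanoparticles with hydroxyl groups on their surface) at 50 μg/mL or with vehicle. The study asked what toxic effect these particles have on esophageal epithelial cells. There were 3 arrays per group, with 26456 to 29726 of 58201 probes well above background per array. Over the 16105 tested genes, arrays of the same group correlated at 0.988 to 0.993 (vehicle) and 0.992 to 0.996 (GQD), and arrays of different groups at 0.919 to 0.941. Vehicle 3, which shares a slide with the GQD arrays, correlated with them at 0.934 to 0.941. Vehicle 1 and vehicle 2, on the other slide, did so at 0.919 to 0.931. All fold changes below are relative to each array's 75th percentile, that is, to the bulk of the sample's own transcripts.

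In cells given GQD, the gene lists of stress responses and immediate early genes had higher medians and those of cell division had lower medians than in cells given vehicle. None of these lists passed with an estimated correlation (adjusted p = 0.70 for each). The transcription factor gene ATF3 rose 37.2-fold (log2 fold change 5.22 ± 0.10, SE, 3 arrays per group, limma adjusted p = 5.01e-06) and the heme oxygenase gene HMOX1 34.4-fold (5.10 ± 0.12, adjusted p = 5.11e-06). Of 4 tested probes of ATF3, 1 did not pass, with a log2 fold change of 0.40 (adjusted p = 0.202). SH3PXD2A, which encodes an adaptor protein of invadopodia, fell 29.7-fold (log2 fold change -4.89 ± 0.10, adjusted p = 5.01e-06). With limma, 6028 of 16105 genes were higher and 5175 were lower at an adjusted p under 0.05. By at least 2-fold, 2428 genes were higher and 2243 were lower. The values of the groups did not overlap for 12050 genes (74.8%). Chance gives 10% for any one gene taken alone. Genes measured on the same arrays are not independent, so the share over all genes cannot decide whether chance is excluded.

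The other large rises among genes well above background on all 6 arrays were as follows. EGR4 rose 25.5-fold, JUN 25.2-fold, ZNF44 20.8-fold and CSRNP1 13.4-fold, all of which encode transcription factors or nuclear DNA-binding proteins. GADD45G, a growth arrest gene, rose 21.6-fold, and PPP1R15A, whose product directs dephosphorylation of the translation factor eIF2α, rose 17.8-fold. OASL, an interferon-induced gene, rose 19.0-fold, and the matrix protein gene MATN4 12.6-fold. The small heat shock protein gene HSPB8 rose by a log2 fold change of 3.81. The SE of these log2 fold changes was 0.079 to 0.14. A second tested probe of ZNF44 gave a log2 fold change of 0.51 against 4.38 for the probe used. On build hg19 (GRCh37), the probe of ATF3 lies on chromosome 1 from 212793856 to 212793915, that of HMOX1 on chromosome 22 from 35790122 to 35790181, and that of JUN on chromosome 1 from 59246511 to 59246570.

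Among the large falls, the log2 fold change was -3.83 ± 0.24 (SE) for the amino acid transporter gene SLC6A14, -3.78 ± 0.11 for the elongation factor kinase gene EEF2K and -3.77 ± 0.11 for SCAI, a suppressor of cancer cell invasion. It was -3.72 ± 0.16 for the metabolic enzyme gene D2HGDH, -3.71 ± 0.12 for the cell division cycle gene CDCA7, -3.47 ± 0.12 for the receptor kinase gene GRK3 (ADRBK2 in the array design) and -3.41 ± 0.10 for the semaphorin receptor gene PLXNA1. ATG16L2, ZNF767P (a pseudogene), PLEKHH1 and the mitochondrial iron importer gene SLC25A37 fell 10.5-, 10.2-, 9.90- and 9.86-fold. A second probe of D2HGDH, at the 5′ end of its transcript, rose by a log2 fold change of 0.53, and a second probe of SCAI fell by only 0.76. Second probes of CDCA7 and SLC25A37 fell by 1.81 and 1.24, and other probes of ZNF767P by 1.87 and 1.02. The probe of SH3PXD2A lies on chromosome 10 from 105353894 to 105353953 (hg19) and starts at base 11077 of its transcript. That of SCAI starts at base 11890. EEF2K, GRK3, PLXNA1 and PLEKHH1 had 1 tested probe each, starting at bases 7322, 8975, 8972 and 5893. Of all tested genes with a probe start beyond base 5000, 40.6% fell by at least 2-fold. A second probe of SH3PXD2A, starting at base 5482, fell by 4.43 on the log2 scale. For genes with 1 tested probe, whether the fall holds for the whole transcript was not tested. Further probes, where a gene had them, show only the positions they cover.

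**Figure D1:**
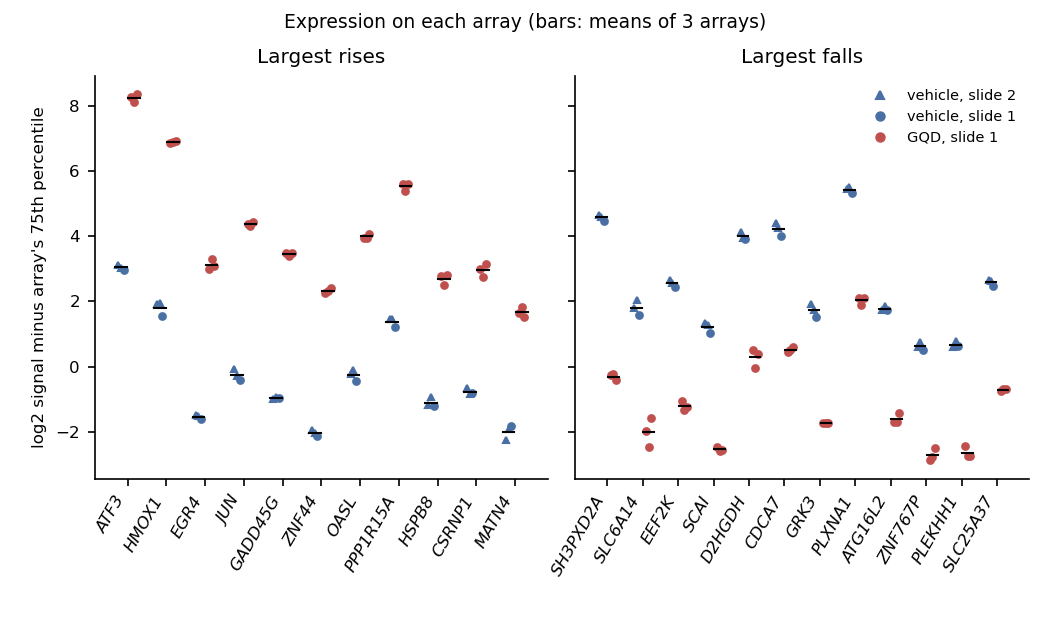
The log2 signal of each array, after subtraction of the array's 75th percentile, is plotted for 11 genes with large rises (left) and 12 with large falls (right), with vehicle in blue, GQD in red, triangles for slide 2, circles for slide 1 and bars for the means of 3 arrays. The genes were chosen by the size of their change and for having no overlap between the groups, with log2 fold changes from -4.89 for SH3PXD2A to 5.22 for ATF3.

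Several genes passed from not well above background on any array of a group to well above it on all 3 arrays of the other. By their brightest probes, the GABA transporter gene SLC6A13 was at least 30.2-fold higher in GQD (adjusted p = 1.68e-05), CCN2, which encodes a matricellular protein (CTGF in the array design), at least 15.9-fold, the amine oxidase gene AOC3 at least 12.4-fold and the skeletal actin gene ACTA1 at least 10.2-fold. In the other direction, also by the brightest probe, the coactivator gene PPARGC1B was at least 15.8-fold lower (adjusted p = 1.46e-05), the splicing-associated gene U2SURP at least 13.9-fold, the granulocyte growth factor gene CSF3 at least 12.2-fold and PSD3 at least 11.6-fold. Second probes changed the same way but less, with log2 fold changes of 3.26 for SLC6A13, -3.00 for PPARGC1B, -2.39 for CSF3 and -2.46 for PSD3. The only tested probe of U2SURP starts at base 6556, and the brightest probes of PPARGC1B and PSD3 at bases 10516 and 11387. In all, 222 genes were well above background on all GQD arrays and no vehicle array, and 225 the other way round.

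Genes of cell division fell together. Of 34 measured genes of mitosis and G2/M, 32 fell and none rose (33 fell when adjusted over the list alone), with a median log2 fold change of -1.03 and a camera adjusted p of 1.88e-08. TOP2A, encoding a topoisomerase, fell 6.27-fold, the phosphatase gene CDC25B 4.65-fold, and the mitotic kinesin genes KIF11 and CENPE 3.62- and 3.54-fold. Of 33 genes of DNA replication and S phase, 25 fell and 0 rose (median -0.90, camera adjusted p = 1.24e-06). Among them POLE2, a subunit of DNA polymerase epsilon, fell 6.31-fold, the replication factor gene MCM10 4.41-fold, the ligase gene LIG1 3.05-fold and RFC4 3.02-fold. Of 28 DNA damage repair genes, 20 fell and 3 rose (median -0.68, camera adjusted p = 0.000413). PRKDC, RAD54L, XRCC2 and BRCA2 fell 5.08-, 4.39-, 3.32- and 3.30-fold. The tested probes of PRKDC start at bases 12633 and 12817, and the only tested probes of BRCA2 and CENPE at bases 10572 and 8176. Falls were common for probes that far along a transcript, as described below. Of 29 ribosome biogenesis genes, 18 fell and 2 rose (median -0.39, -0.62 after quantile normalization, camera adjusted p = 0.00747), with BOP1 3.54-fold and MYBBP1A 2.74-fold lower. None of these 4 calls held with an estimated correlation (adjusted p = 0.70 for each). With slide as a block the medians were -0.92, -0.75, -0.63 and -0.23, in the order given, and each list stayed past the threshold.

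Stress response genes rose as groups. Of 24 immediate early and growth factor response genes, 17 rose and 3 fell (18 and 3 adjusted over the list alone; median 1.33, camera adjusted p = 0.000603). They included EGR1, which rose 10.9-fold, and EGR2, which was well above background on 1 vehicle array and all 3 GQD arrays. Of 25 integrated stress response and ATF4 targets, 16 rose and 3 fell (median 0.76, 0.49 after quantile normalization, camera adjusted p = 0.00647). DDIT3, encoding the stress transcription factor CHOP, rose 10.2-fold, whereas DDIT4, an inhibitor of mTOR signalling, fell 9.33-fold. Of 27 NRF2 and glutathione targets, 21 rose and 3 fell (median 0.75, 0.47 after quantile normalization, camera adjusted p = 0.000748), with OSGIN1 5.47-fold, the thioredoxin reductase gene TXNRD1 4.88-fold and the glutathione reductase gene GSR 3.25-fold higher. Of these lists too, none held with an estimated correlation (adjusted p = 0.70 for each). With slide as a block their medians were 1.46, 0.89 and 0.72, and the calls stayed.

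Of 20 heat shock protein genes, 13 rose and 1 fell (median 0.67, camera adjusted p = 0.00926). CRYAB rose 2.87-fold, HSPB1 2.73-fold and DNAJB1 2.15-fold. Of 17 antioxidant enzyme genes outside the NRF2 list, 12 rose and 1 fell (median 0.61, 0.17 after quantile normalization, camera adjusted p = 0.0191), with the superoxide dismutase genes SOD3 and SOD2 3.16- and 2.57-fold higher and PRDX5 1.90-fold higher. Neither list passed after quantile normalization (adjusted p = 0.0918 and 0.122) or with an estimated correlation (adjusted p = 0.70 for each). With slide as a block both passed, at medians of 0.86 and 0.63. Metallothionein genes, which respond to metals, went mainly the other way, with 5 of 9 lower and 2 higher (median -0.55, -1.15 after quantile normalization), and the list did not pass (camera adjusted p = 0.271). MT1X fell 2.06-fold and MT1E 1.88-fold. MT3 rose 1.66-fold but did not pass with slide as a block (adjusted p = 0.379).

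Of 28 interferon-stimulated genes, 21 rose and 1 fell, at a median log2 fold change of 1.44 (camera adjusted p = 8.73e-05, and 0.70 as adjusted p with an estimated correlation). RSAD2 was not well above background in vehicle and was at least 10.2-fold higher in GQD, ISG15 rose 6.27-fold, and IFI44L, well above background on 2 of 3 vehicle arrays, rose 5.17-fold. With slide as a block the median was 1.58. Of 27 NF-kB targets and inflammatory cytokine genes, 14 rose and 6 fell (median 0.51), which did not pass (camera adjusted p = 0.0914). CSF2 rose 7.25-fold and CXCL8 5.05-fold, CCL5 was well above background on 1 vehicle array and all GQD arrays, and CSF3 was no longer well above background by its brightest probe.

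All 36 measured cytosolic ribosomal protein genes rose (median 0.69, camera adjusted p = 1.69e-07), led by RPS23 with a 2.00-fold rise. The median was 0.09 and the list did not pass after quantile normalization (adjusted p = 0.333), and the adjusted p was 0.092 with an estimated correlation. Probes of this family can also bind pseudogene copies. Of 27 proteasome subunit genes, 20 rose and 0 fell (median 0.66, 0.28 after quantile normalization, camera adjusted p = 0.000442), with PSMB2 2.34-fold and PSMB7 2.13-fold higher. Of 36 autophagy and lysosome genes, 20 rose and 3 fell (median 0.50, camera adjusted p = 0.0447). The autophagosome genes GABARAPL1 and SQSTM1 rose 6.61- and 5.12-fold. UVRAG fell 3.68-fold by its only tested probe, which starts at base 5083 of its transcript. Of 14 histone genes, core and linker, 10 rose and 1 fell (median 0.42, camera adjusted p = 0.0489). H2AC8 (HIST1H2AE in the array design) rose 2.85-fold and the linker histone gene H1-3 (HIST1H1D) fell 2.34-fold. Proteasome, autophagy and histone lists were lost with an estimated correlation (adjusted p = 0.70 for each). The autophagy and histone lists were also lost after quantile normalization (adjusted p = 0.0918 and 0.152), and the histone list with slide as a block (adjusted p = 0.107). With slide as a block the medians of the ribosomal, proteasome, autophagy and histone lists were 0.64, 0.74, 0.65 and 0.38.

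**Figure D2:**
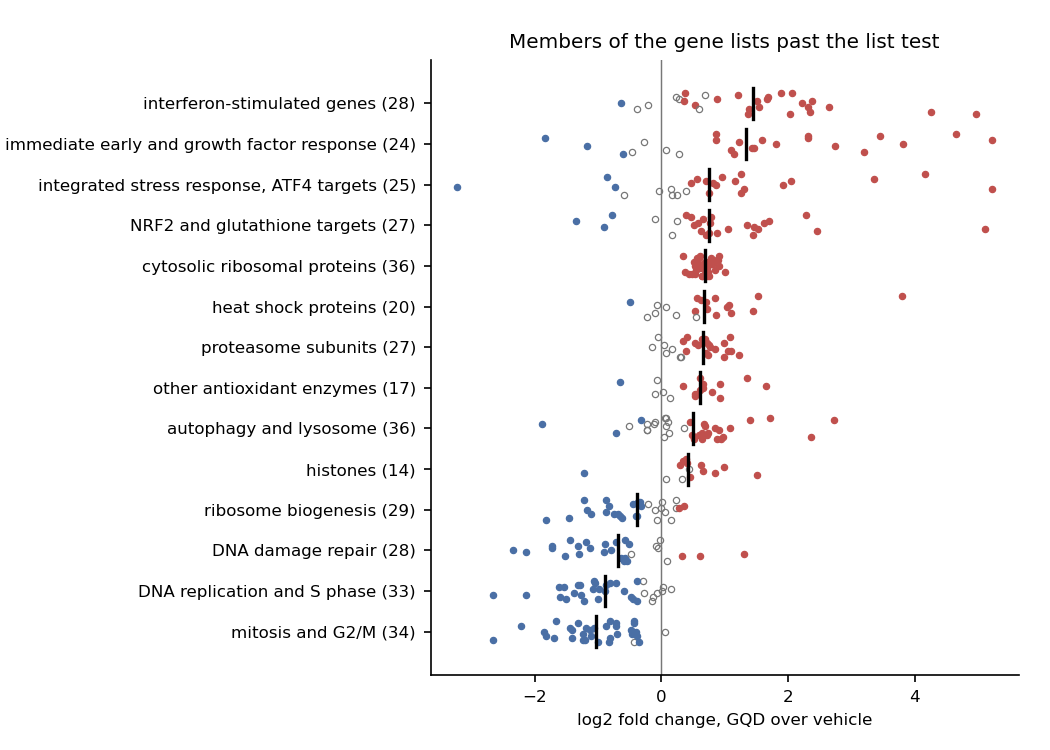
Each point is the log2 fold change (GQD over vehicle, relative to each array's 75th percentile) of a member of the 14 gene lists past the camera test, with the number of measured members in brackets, filled points for genes past an adjusted p of 0.05 (red higher, blue lower) and bars for medians. Mitosis genes lie around a median of -1.03 and interferon-stimulated genes around 1.44, while ribosomal protein genes lie close together around 0.69 (0.09 after quantile normalization), and none of the 14 lists passed with an estimated correlation (adjusted p = 0.092 to 0.70).

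The lists on p53, cell cycle inhibitors and apoptosis held large changes in both directions and did not pass. Of 26 p53 targets, 15 rose and 5 fell (median 0.68, camera adjusted p = 0.114). GADD45A rose 4.88-fold and GDF15 3.78-fold, while CCNG1 fell 4.93-fold by its brightest probe and was not called by a second probe (log2 fold change -0.43, adjusted p = 0.0827). Of 14 cell cycle inhibitor and senescence genes, 9 rose and 4 fell (median 0.56, 0.36 after quantile normalization, camera adjusted p = 0.206), with CDKN1C 7.20-fold and CDKN1A 3.55-fold higher and LMNB1 3.87-fold lower. Of 30 BCL2 family and caspase genes, 15 rose and 8 fell (median 0.24, 0.40 with slide as a block, camera adjusted p = 0.345). PMAIP1 and BBC3, which encode the proapoptotic proteins NOXA and PUMA, rose 12.3- and 2.89-fold. XIAP, a caspase inhibitor, fell 3.40-fold by a probe that starts at base 8324 of its transcript, while a probe at base 1710 gave a log2 fold change of 0.07 (adjusted p = 0.512).

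Genes of matrix, cell shape and epithelial identity also went both ways. Of 17 genes of the epithelial to mesenchymal transition, 8 rose and 4 fell (median 0.33, 0.18 after normexp with quantile normalization, camera adjusted p = 0.271), with SNAI1 12.3-fold and OVOL1 4.31-fold higher. TWIST2 fell 5.80-fold by its brightest probe, while a second probe gave a log2 fold change of -0.0637 (adjusted p = 0.773). Of 29 TGF-beta target and extracellular matrix genes, 12 rose and 9 fell (13 and 9 adjusted over the list alone; median 0.27, 0.13 after normexp, camera adjusted p = 0.37), COL6A1 by a 3.50-fold rise and TIMP3 by a 3.22-fold fall. Of 29 actin cytoskeleton and focal adhesion genes, 10 rose and 8 fell. Their median of -0.09 (-0.27 after quantile normalization, 0.07 after centring on the median of tested genes) and the camera direction were down, their mean of 0.01 and the fry direction were up, and the list did not pass (camera adjusted p = 0.726). TPM4, a tropomyosin gene, rose 4.62-fold. Of 27 tubulin and microtubule protein genes, 13 rose and 3 fell (11 and 3 adjusted over the list alone; median 0.24, -0.10 after quantile normalization, camera adjusted p = 0.206), with TUBB2A 4.44-fold higher by its brightest probe and not called by a second probe (log2 fold change 0.43, adjusted p = 0.236). Of 25 squamous epithelial markers, 10 rose and 5 fell (10 and 4 adjusted over the list alone; median 0.24, 0.0143 after quantile normalization and -0.0342 after normexp with quantile normalization, camera adjusted p = 0.386). KRT6A and KRT6B fell 4.27- and 2.44-fold, and DSC2 rose 2.91-fold. All 4 simple epithelial keratin genes measured rose, KRT8 2.35-fold and KRT18 2.15-fold, whereas KRT7 and KRT19, with log2 fold changes of 0.41 and 0.30, turned to -0.23 each after quantile normalization, and KRT19 did not pass with slide as a block (adjusted p = 0.0605).

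Metabolic lists did not pass. Of 14 fatty acid synthesis and desaturation genes, 8 fell and 4 rose (median -0.62, -0.26 with the mean of all probes of a gene, camera adjusted p = 0.163). ACACA fell 3.78-fold by a probe starting at base 10596, and rose by a log2 fold change of 1.64 by a probe starting at base 1340. Of 24 cholesterol synthesis genes, 9 rose and 3 fell (6 and 2 adjusted over the list alone; median 0.17, -0.03 after quantile normalization, camera adjusted p = 0.297), with STARD4 2.53-fold higher. Of 28 glycolysis and hypoxia targets, 12 rose and 7 fell (9 and 4 adjusted over the list alone; median 0.14, -0.21 after quantile normalization, camera adjusted p = 0.601), with the adrenomedullin gene ADM 10.5-fold higher. Of 36 nuclear genes of oxidative phosphorylation, 19 rose and 5 fell (median 0.30, -0.01 after quantile normalization). This list did not pass (camera adjusted p = 0.0651), but passed with slide as a block (median 0.38, adjusted p = 0.0235). NDUFA6 rose 2.12-fold. Of 9 aryl hydrocarbon receptor targets, 4 rose and 3 fell (median 0.42, camera adjusted p = 0.601), with CYP1A2 3.23-fold higher.

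Of 25 endocytosis genes, 12 rose and 7 fell (median 0.15, -0.10 after quantile normalization, camera adjusted p = 0.586), with CLTB and FLOT1 5.24- and 5.23-fold higher and EPN2 4.23-fold lower. Of 20 endoplasmic reticulum chaperone genes, 9 rose and 7 fell (median 0.16, -0.01 after quantile normalization, camera adjusted p = 0.533). DNAJB9 and HERPUD1 rose 3.29- and 2.95-fold. Of 14 housekeeping genes, 8 rose and 5 fell (median 0.37, -0.22 after quantile normalization, camera adjusted p = 0.599), with TFRC 3.08-fold lower.

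The tested lists of markers of other cell types did not pass camera, though their medians were above 0 and each passed upwards with fry (adjusted p = 0.0438 for leukocytes, 0.0269 for endothelium and 0.00944 for glandular and liver markers). Of 11 leukocyte markers, 7 rose and 2 fell (8 and 2 adjusted over the list alone; median 1.03, 0.45 with slide as a block, camera adjusted p = 0.258), with CD79A 2.63-fold higher and LAPTM5 3.76-fold lower. Of 7 glandular and liver markers, 4 rose (median 0.85, 0.61 with slide as a block, camera adjusted p = 0.204), among them APOA1 by 3.06-fold. Of 5 endothelial markers, 1 rose and 1 fell (median 0.62, 0.01 with slide as a block, camera adjusted p = 0.708). Of 4 fibroblast markers, 2 rose and 1 fell (median 0.07, mean -0.02), COL1A1 by a 1.92-fold fall. Counts adjusted over the list alone that are not given were the same as those over all genes. The 21 tested lists that did not pass also missed the threshold with an estimated correlation (adjusted p = 0.70 to 0.81).

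The fold change depended on where in the transcript a probe lay. Genes whose probe started within the first 500 bases had a median log2 fold change of 0.59, and 27.4% of these 2041 genes rose by at least 2-fold. The 1455 genes whose probe started beyond base 5000 had a median of -0.74, and 40.6% fell by at least 2-fold. In 2212 transcripts with probes more than 500 bases apart, the 3′ probe had a fold change lower than the 5′ probe by a median of 0.57 on the log2 scale (difference -0.574, 95% bootstrap interval -0.625 to -0.519). The 3′ probe was the lower in 71.8% of pairs. Of 4625 genes with several tested probes, 787 had probes called in both directions. Among genes named above, further probes gave log2 fold changes of 0.52 for GSR, 0.37 for HSPB1 (adjusted p = 0.082), 0.40 for RPS23, 0.27 for DSC2 (adjusted p = 0.0563) and -1.02 for EPN2. Set against genes with a like probe start, the medians that shrank by more than 1.5 times among lists past camera were those of ribosomal protein genes (0.20), histone genes (-0.06), antioxidant enzyme genes (0.28), proteasome genes (0.39) and NRF2 targets (0.46). Those of mitosis genes (-1.02), DNA replication genes (-0.80), DNA repair genes (-0.81), ribosome biogenesis genes (-0.43), interferon-stimulated genes (1.48), immediate early genes (1.22), heat shock protein genes (0.66), ATF4 targets (0.62) and autophagy genes (0.46) moved less.

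**Figure D3:**
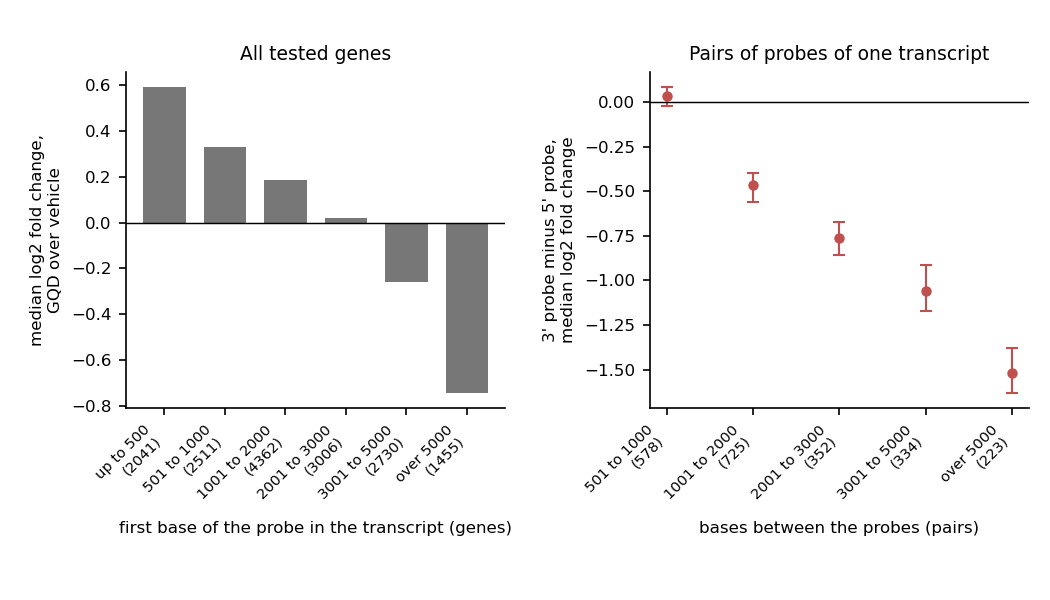
The left panel shows the median log2 fold change (GQD over vehicle) of tested genes by the first base of their probe in the transcript, with the number of genes in brackets, and the right panel the median difference between the 3′ and the 5′ probe of a transcript by their distance, with 95% bootstrap intervals and the number of pairs. The median goes from 0.59 for the most 5′ probes to -0.74 beyond base 5000, and the difference within transcripts from 0.03 at up to 1000 bases to -1.52 over 5000 bases.

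Spike-in probes, which detect control RNAs added in known amounts to a labelling reaction, were brighter against the sample on the GQD arrays. Over 5 of 10 kinds of spike-in probe (the 3 brightest and 2 not well above background on all arrays were left out), the mean log2 signal over the array's 75th percentile was 2.75 ± 0.27 (SD, n = 3) on vehicle arrays and 4.33 ± 0.53 (SD, n = 3) on GQD arrays. The difference was 1.58 (exact permutation test, two-sided p = 0.1, the smallest that 3 against 3 can give). Scaled to these probes, each log2 fold change is lower by 1.58, the median of all genes is -1.48 in place of 0.10, and the medians of all tested lists are below 0.

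**Figure D4:**
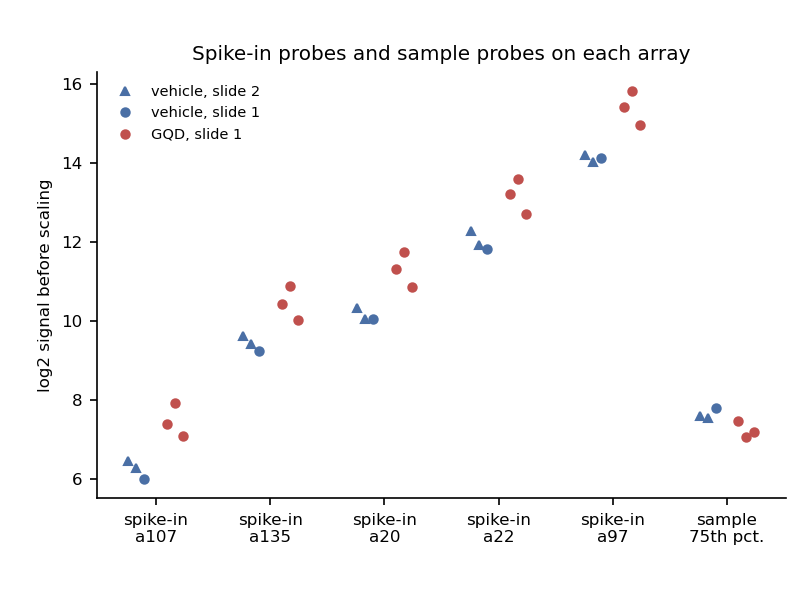
The log2 signal before scaling is plotted for 5 kinds of spike-in probe and for the 75th percentile of the sample probes on each array, with vehicle in blue, GQD in red, circles for slide 1 and triangles for slide 2. Each kind of spike-in probe is brighter on the 3 GQD arrays, by 1.02 to 1.27, while the sample's 75th percentile is lower on them by a mean of 0.407 (difference -0.407).

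The slide that holds both groups allowed a comparison within it. With slide as a block, 5070 genes were higher and 4032 lower, and 4237 of the 4671 genes changed by at least 2-fold kept their call and direction. In that fit, which rests on 1 vehicle array, the log2 fold change was 5.285 for ATF3 and -4.79 for SH3PXD2A. The genes named for the size of their change had been picked on these same arrays for separation of the groups. Their result with slide as a block is therefore no separate support for them. Processing moved the balance of calls. Of the genes changed by at least 2-fold, 52% were higher, against 63.3% after centring on the median of tested genes 45.2% after quantile normalization, 43.8% after normexp and 41% after normexp with quantile normalization. Of all called genes, 53.8% were higher, against 2.1% with spike-in scaling, which was chosen after seeing the data. The median of all genes was 0.26 after centring on the median and -0.02 after quantile normalization.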

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

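The tests for RNA degradation and for longer labelled products and the 3 tests on the spike-in probes were chosen after the results were seen, as were the comparisons of probe pairs and of spike-in probes themselves. The groups hold 3 arrays each, too few to test single arrays as outliers.

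Spike-in probes, which are control spots left out of the gene tests, stood 1.58 log2 units higher over the 75th percentile on the GQD arrays than on the vehicle arrays. A slide difference is argued against, since vehicle 3 shares the slide of the GQD arrays and lay 1.5 log2 units below the lowest of them. Brighter hybridisation or scanning is argued against as well, since the 75th percentile of the sample probes differed by -0.407 between GQD and vehicle and was lower on every GQD array than on every vehicle array. The shift was alike for the 5 kinds of spike-in probe used (SD 0.0944 on the log2 scale; 0.378 to 1.56 for the 5 left out as brightest or dimmest), which is consistent with less sample RNA against spike-in RNA in the labelling reaction. That test does not separate a lower share of polyadenylated RNA in treated cells from less RNA, or more spike-in, put into the reaction, so whether most transcripts fell per cell stays open.

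Probes not used for their gene gave a second signal: within a transcript, the 3′ probe had a log2 fold change lower than the 5′ probe, with a median difference of -0.574. Degraded RNA in the GQD samples would lower 5′ probes when labelling starts at the poly(A) tail, which is the opposite sign. The sign does not argue against less intact RNA in the vehicle samples, which was not tested. At equal probe GC content and brightness the difference was -0.715 (95% interval over pairs -0.765 to -0.664). On slide 1 alone, with 1 vehicle array, it was -0.503. On these arrays, neither these probe properties nor the slide accounts for it. Longer labelled products in the GQD samples would leave the most 3′ probes in place. Of the most 3′ probes, those starting beyond base 5000 lay -1.32 from those starting before base 1000. These probes belong to different genes, and their start is counted from the 5′ end and not from the poly(A) tail. The test therefore cannot decide on longer products. Pairs within one exon showed a median difference of -0.726, and pairs across exons one of -0.507. That more transcripts ended upstream of the 3′ probe in treated cells is a candidate explanation. The one-exon test cannot single it out, since any other effect of probe position would also appear within an exon. Whether a smaller amount of RNA in the labelling reaction can give this pattern was not tested.

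Among 6654 tested probes with no gene symbol, 1639 (24.6%) were higher in GQD by at least 2-fold and 641 (9.63%) were lower, against 15.1% and 13.9% of named genes. The first shares count single probes, while each named gene counts once, by its brightest probe. Among 1530 named long noncoding RNA genes, 389 were higher and 139 lower by at least 2-fold, so the excess of rises was not particular to unnamed probes.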

How the results depend on the processing

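The settings below were compared with the values of 162 named genes and of the gene lists. Of 3547 comparisons of single genes, 3410 kept direction and side of the threshold, 75 lost the threshold and 62 turned direction, and of 839 comparisons of lists, 743 kept both. Leaving out 1 array at a time gave 5259 to 5964 genes higher and 4599 to 5280 lower by limma at an adjusted p under 0.05. By at least 2-fold it gave 2306 to 2622 higher and 2161 to 2400 lower, with 8 to 10 gene lists higher and 4 lower. The autophagy list was lost without vehicle 1 (adjusted p = 0.0553) or vehicle 3 (0.09), and the histone list without vehicle 1 (0.0867), vehicle 2 (0.052) or GQD 2 (0.0558), where the oxidative phosphorylation list passed instead (0.044). Normexp background correction, which shrinks folds of dim genes by its offset, gave 1103 genes higher and 1414 lower by at least 2-fold, and 1000 and 1437 with quantile normalization. The gene lists higher in GQD were 10 in the report, 5 with quantile normalization, 6 with normexp and quantile normalization, 5 with the deposited table and 28 with fry. With an estimated correlation 0 lists were higher and 0 lower. KRT7 turned to -0.23, -0.22 and -0.24 and KRT19 to -0.23, -0.23 and -0.23 with quantile normalization, normexp with quantile normalization and the deposited table; the cause was not tested. Genes near background limit these values, since their folds depend on the background correction.

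With replicate number as a block, 5659 genes were higher and 4807 lower. The numbers gave no sign of pairing, since arrays with the same number correlated at 0.05, -0.12 and -0.16 after removal of the group means, and no vehicle array correlated best with its own number. The autophagy and histone lists lost their call with this block (adjusted p = 0.0557 and 0.0596), and no other list did.

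The other settings were added after seeing the data. Scaling to the spike-in probes, which lowers every log2 fold change by 1.58, gave 263 genes higher and 12266 lower, 210 and 11367 by at least 2-fold. With it camera placed 6 gene lists above the other genes, but their medians were below 0 too, so that they were lowered less. It turned the direction of 48 named genes: SOD2 -0.22, PRDX5 -0.65, GLRX -0.66, MT3 -0.85, HERPUD1 -0.016, CANX -0.39, DNAJB11 -0.80, CRYAB -0.0586, HSPB1 -0.13, DNAJB1 -0.47, CDKN2A -0.12, TUBB3 -0.062, MAP4 -0.26, H2AC8 -0.0662, H2AC6 -0.58, H4C8 -0.73, BBC3 -0.0485, STARD4 -0.24, INSIG1 -0.42, IDI1 -0.44, SLC2A3 -0.64, NDUFA6 -0.49, COX6C -0.57, COX6A1 -0.60, UQCRB -0.66, AHRR -0.42, UGT1A6 -0.85, DSC2 -0.0377, KRT4 -0.31, KRT8 -0.34, KRT18 -0.48, KRT7 -1.17, KRT19 -1.28, RPS23 -0.58, RPL14 -0.67, RPS29 -0.67, PSMB2 -0.35, PSMB7 -0.48, PSMC1 -0.50, PSMD2 -0.53, RPLP0 -0.79, CD79A -0.19, CD3D -0.20, EGFL7 -0.57, FBLN1 -0.85, DPT -1.23, MUC2 -0.54, CDX1 -0.72. The probe nearest the 5′ end turned D2HGDH to 0.53, CLASP2 to 0.36, XIAP to 0.0734 and ACACA to 1.64. The probe nearest the 3′ end turned CANX to -0.60, MAP4 to -0.53, SREBF1 to 0.33 and FBLN1 to -0.29. Both choices put another probe in place of the brightest; why the probes of these genes differ was not tested.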

Other observations

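The gene families in the next paragraph and the tests in the last were chosen after the data were seen.

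Small nucleolar RNA genes, whose products guide modification of ribosomal RNA, rose as a family in cells given GQD. Of 216 measured, 189 rose and 6 fell, with a median log2 fold change of 1.27 (1.26 with slide as a block, and -0.31 with spike-in scaling). Their camera adjusted p over 9 families was 5.27e-18, and the adjusted p was 0.34 with an estimated correlation. SNORD84 rose 11.1-fold, SNORD46 7.98-fold and SNORD43 6.46-fold, with the caveat that these RNAs are not polyadenylated in their mature form. The median exceeded that of 1822 other genes whose probe starts before base 500 by 0.73 (95% bootstrap interval over genes 0.57 to 0.91). Of 1530 long noncoding RNA genes, 740 rose and 267 fell (median 0.51, 0.37 with slide as a block, camera adjusted p = 0.00463, adjusted p = 0.34 with an estimated correlation). Among them LINC-PINT rose 13.0-fold. Of 22 dual specificity phosphatase genes, 12 rose and 1 fell (median 0.53, 0.80 with slide as a block, camera adjusted p = 0.0484, adjusted p = 0.52 with an estimated correlation). The other 6 families tested did not pass.

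With 3 arrays against 3 there are 10 splits, too few for a share under 0.05. The real split called 11203 genes and was the 1 split with a count that large. The highest of the other 9 splits called 0 genes by limma at an adjusted p under 0.05, with 33 to 201 genes at an unadjusted p under 0.05. Each of these 9 splits mixes GQD and vehicle arrays on both sides. The group difference then adds to the spread, so their low counts lend no support to the real split. The first test for a slide difference took the 5022 genes called at 2-fold without vehicle 3. Of these, 4398 (87.6%) changed the same way by at least 50% as much between vehicle 3 and the GQD arrays, which lay between the bounds set for it (under 50% for a slide difference, over 90% against it) and decided nothing. A second test, chosen after the first was seen, asked how many genes kept their call with slide as a block. It gave 90.7% of the 4671 genes changed by at least 2-fold, and 434 genes lost their call. With the block, the log2 fold changes of these 434 genes were a median of 0.565 times as large and their SE 1.17 times as large, against 0.954 and 1.3 for the genes that kept their call. Since they were picked by losing it, and the block rests on 1 vehicle array, how much of their difference came from the slide stays open.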
